A study of Arabidopsis thaliana with 24 samples.

How the data were processed

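RNA from leaves was hybridised to 24 one-colour (Cy3) Agilent arrays, 1 sample per array, in 8 groups of 3 biological replicates (2 genotypes at 4 times). Per the labels, each sample pooled leaves of 8 plants grown in 16 h of light and 8 h of dark, the bacteria were syringe-infiltrated at an OD600 of 0.001 in 10 mM MgCl2, and 200 ng of RNA were labelled. Per the file headers, the scanner files hold intensity values from Agilent Feature Extraction 10.1.1.1, and 3 kinds were used. The processed signal is an intensity with background subtracted and trends within the array removed, and the mean signal and local background are intensities before any correction. The deposited scanner files also hold flags for each spot (well above background, saturated, outlier). The authors' series table holds log2 values. It follows the rank of the median signal minus local background within each array, its quartiles nearly coincide between arrays (medians 9.07 to 9.10), and R 2.15.2 is named for it, but the steps are not given in the sources used here. All 24 of its columns belong to a sample.

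Of 43603 gene probes, 37540 name 1 locus, 873 several and 5190 none, and 28074 of 28479 loci matched the table that gave the gene symbols. The 1417 control spots and 687 gene spots with an outlier flag (over all arrays) were left out, and saturated spots (0 to 29 per array) were kept. The log2 processed signal was scaled by subtracting each array's 75th percentile (1320.6 to 4413.5 before the log), so a change is relative to the array. A gene was represented by its probe with the highest mean, and was tested where that probe was well above background on at least 2 of 3 arrays of a group, which left 25230 of 33700 genes. The depth of an array is its signal over background, and 3 arrays per group limit the precision. Where the dimmer group had probes not well above background, the fold is a lower bound, "at least N-fold". It compares the mean of the brighter group with the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal among probes well above background on that array.

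limma 3.58.1 (in R 4.3.3, with statmod 1.5.0 and version 1.17.8 of data.table) fitted 8 group means to all 24 arrays, with moderated variances. The 13 comparisons were each time against 0 h within a genotype, the genotypes at each time, and the difference of these changes between genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and the SE printed is limma's. Among called genes named in the 10 pairwise comparisons, only PR5 (Col-0, 12 h) and MED14 (0 h) had groups with overlapping arrays. The naming rule required no overlap for some of them, so this is no separate check. The highest adjusted p of a called gene named in the report was 0.0239 (0.0365 in the closing section), and where none is printed beside a gene there it was lower. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists of a comparison. There were 23 lists (SA and pipecolate, SA-dependent pathogenesis-related, jasmonate and ethylene defence, jasmonate synthesis and signalling, pattern-triggered immunity, camalexin and indole glucosinolates, aliphatic glucosinolates, photosynthesis, other Mediator subunits, cell cycle, cold, abscisic acid, auxin, endoplasmic reticulum, senescence, morning and evening clock, heat shock and handling, guard cell, vascular, epidermis, seed and reference genes) and 11 families taken from the annotation (WRKY, NAC, MYB, TIR-NBS-LRR, cysteine-rich and wall-associated kinases, glutathione S-transferases, UDP-glycosyltransferases, heat shock proteins, histones and cytosolic ribosomal proteins). Of 70 list results past the threshold, 6 passed with an estimated correlation, all in Col-0 at 4 h. Of these, heat shock was lost with genes well above background on all 24 arrays. SA and pipecolate, pattern-triggered immunity, camalexin, WRKY and NAC had adjusted p up to 0.0494 over all alternatives. For 63 of the 64 others the estimated correlation gave the highest p.

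Comparisons, tests, gene lists and alternatives were chosen before the data were examined, except normexp with one background per array and the tests of MED14 and of Col-0 0 h replicate 3 in the closing section, which were chosen after seeing the data. So were FLC and SEP1. The text names other genes by a rule fixed before: MED14, PR1, PR2, PR5, ICS1, EDS5, NPR1, WRKY38, WRKY70, FMO1, PDF1.2a, PDF1.2b, ORA59 and PAD3; per comparison the 5 called genes with the largest rise and the 5 with the largest fall that carry a name, lie well above background on every array of the brighter group and do not overlap between groups; per list up to 4 members with the smallest adjusted p and any member against the list's direction; and all clock genes in the time comparisons. Not all allowed genes are named. In simulated data with 200 changed genes, pairwise comparisons recovered 62 to 69% of 2-fold changes and differences of changes 48 to 51%. All 13 recovered 86 to 96% of 4-fold changes, with 3 to 15 of 25230 genes called falsely. In the data 9471 to 20165 were called, so these rates may not hold.

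The alternatives were normexp background (offset 50), normexp with one background per array, quantile normalization, the authors' values, no filter on dim probes, genes well above background on all 24 arrays, the mean of all probes, a prior variance with an intensity trend, the arrays compared alone, a replicate block, slide as a block, at least 2-fold, camera with an estimated correlation, fry (which tests a list on its own), and leaving out each array in turn. The array identifiers place 4 arrays on each of 6 slides. Slide was a fixed term in the time comparisons and a random block between genotypes, where each slide holds 1 genotype. All arrays share a scan day, so no block for it was possible. The median change of all genes, -0.28 to 0.00 over the 13 comparisons, was -0.20 to 0.04 with quantile normalization, -0.04 to 0.02 with the authors' values, -0.36 to 0.08 with normexp and one background per array, and -0.65 to 0.46 with normexp. Slopes across genes are major axes, with jackknife errors over arrays.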

Results

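Transcript levels were measured in leaves of Arabidopsis thaliana on 24 one-colour arrays. The plants were the wild type Col-0 and the mutant med14, which is named for subunit 14 of Mediator, the complex that carries signals from transcription factors to RNA polymerase. Leaves were infiltrated with a suspension (OD600 of 0.001) of Pseudomonas syringae pv. tomato DC3000 carrying avrRpt2, an effector gene whose product sets off immunity through the resistance protein RPS2. Samples were taken at 0, 4, 8 and 12 h, with 3 biological replicates for each genotype and time and the leaves of 8 plants in each sample. No mock-infiltrated leaves were among the samples, so a change from 0 h joins infection, infiltration and time of day. Between 66.8% and 73.5% of the gene spots of an array lay well above background, the median signal was 4.61 to 11.33 times the background, and 25230 of 33700 genes were tested. With normexp background every count of called genes below was more than 1.5 times lower, such as 3135 in place of 9471 between genotypes at 0 h and 4563 in place of 13699 at 12 h. The number of arrays, 3 in each group, limits the precision of every value below.

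MED14, the targeted gene, did not follow the labels at 0 h. It has 1 probe, at position 5411 of its transcript (chromosome 3, 1300631 to 1300690, in the genome build that the array files name). A probe outside the part lost in the mutant checks nothing, and the allele is not given in the sources used here. On the 12 arrays labelled med14, the normalized log2 signal lay between -0.96 and -0.60 at all 4 times. On the arrays labelled Col-0 it was 3.76 to 4.31 at 4, 8 and 12 h, but -4.28, -2.33 and -0.47 on the 3 arrays of 0 h (mean -2.36, SD 1.91). MED14 was lower on arrays labelled med14 at 4 h (log2 difference -4.81 ± 0.54 SE, adjusted p = 3.53e-07), 8 h (-4.65, adjusted p = 8.38e-07) and 12 h (-4.83, adjusted p = 7.66e-07). At 0 h it was higher on them (1.64, adjusted p = 0.0225), although the arrays of both labels overlapped. That difference moved to 0.68 without Col-0 replicate 1 (adjusted p = 0.124) and to 2.58 without Col-0 replicate 3 (adjusted p = 2.76e-05). The call was also lost without med14 replicate 1 (adjusted p = 0.0568) or 2 (adjusted p = 0.0522), without Col-0 replicate 2 (adjusted p = 0.0514), with slide as a random block (1.74, adjusted p = 0.0971), and with normexp background, the authors' values and the arrays compared alone (adjusted p = 0.127, 0.124 and 0.214). Genotypes below are those of the labels, which the 0 h arrays do not bear out for this gene, and every direction between genotypes rests on them.

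**Figure D1:**
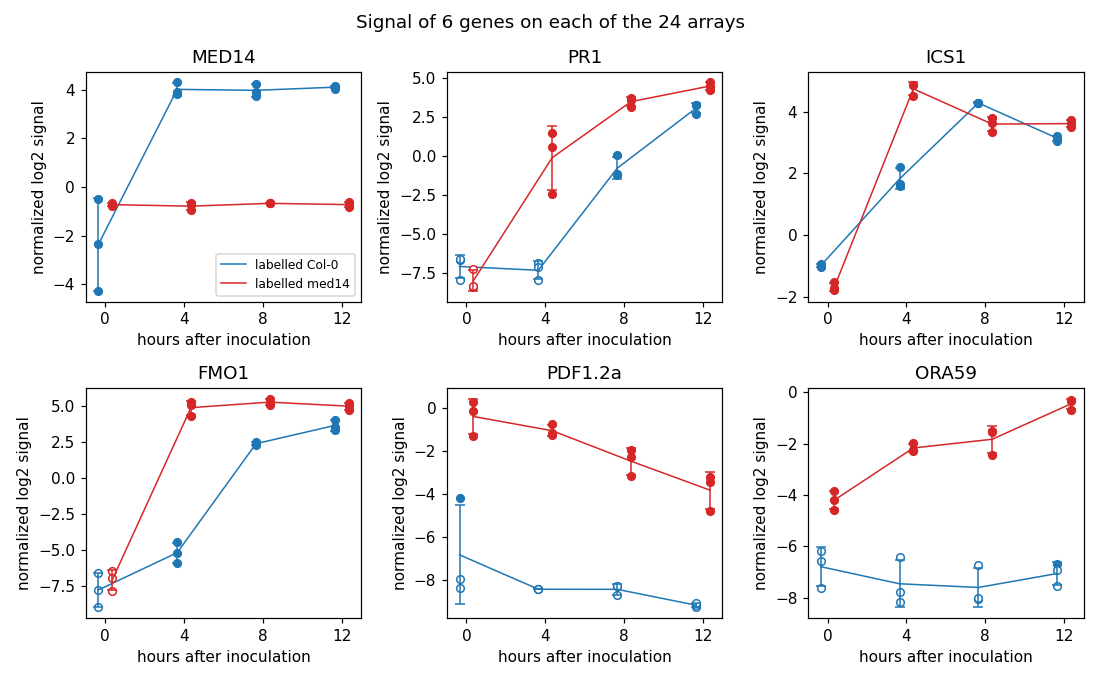
Normalized log2 signal of 6 genes on each array against hours after inoculation, blue for arrays labelled Col-0 and red for arrays labelled med14, with lines through the group means, error bars of 1 SD over 3 arrays, and open circles for spots not well above background. MED14 is above background throughout and highest on Col-0 arrays after 0 h, while PR1 is above background at 4 h only on arrays labelled med14.

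The response of the wild type was read against 0 h. In leaves labelled Col-0, immune genes were already up at 4 h. WRKY46, a salicylic acid (SA) responsive regulator, rose by 7.44 ± 0.15 (log2 change ± SE, 3 arrays against 3), EDS5, which exports the SA precursor from the chloroplast, by 5.46 ± 0.14, and ICS1, which makes that precursor, by 2.80 ± 0.14. PR1, the usual marker of SA signalling, was at background on all arrays of both times, PR2 rose by 1.60 ± 0.42 (adjusted p = 0.00259), and PR5 fell by 1.03 ± 0.20 (adjusted p = 0.000207). MSRB9, a methionine sulfoxide reductase gene, rose by 8.55 ± 0.28, and RAP2.6, an ethylene response factor gene measured on 1 of the 3 arrays of 0 h, at least 487-fold. EXPA8, an expansin that loosens cell walls, fell by 6.10 ± 0.57 and the gibberellin-responsive GASA6 by 5.53 ± 0.59.

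Of the 32 genes of SA and pipecolate synthesis and signalling, 29 rose, 1 fell and 2 did not pass the test (median log2 change 2.64, adjusted p = 3.76e-16), among them SARD1 (6.19 ± 0.15). The 10 SA-dependent pathogenesis-related genes were divided, with 6 up, 1 down and 3 not past the test (median 1.34, adjusted p = 0.0497, or adjusted p = 0.32 with an estimated correlation). That call was also lost without Col-0 0 h replicate 1 (adjusted p = 0.0599) or 2 (adjusted p = 0.0523) or 4 h replicate 2 (adjusted p = 0.0633). All but 2 of the 27 jasmonate genes rose and none fell (median 2.64, adjusted p = 1.63e-12, or adjusted p = 0.0869 with an estimated correlation). AOC3 rose by 6.94 ± 0.32. Of 24 genes of pattern-triggered immunity, 23 rose, including the kinase MPK11 (6.12 ± 0.19) and the NADPH oxidase RBOHD (3.03 ± 0.12), and 1 did not pass (median 2.1, adjusted p = 5.95e-14). Among 19 genes of camalexin and indole glucosinolate synthesis 16 rose, 17 when adjusted over the list alone, and none fell (median 1.77, adjusted p = 3.15e-09). PAD3, the last enzyme of camalexin synthesis, rose at least 33.4-fold.

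Stress and regulatory families moved with them at 4 h in Col-0. Of 15 genes of senescence and cell death 13 rose, 14 when adjusted over the list alone (median 2.68, adjusted p = 5.37e-07, or adjusted p = 0.0741 with an estimated correlation). Of 11 genes of heat shock and handling stress 9 rose, 1 fell and 1 did not pass (median 2.58, adjusted p = 3.14e-05, but 0.0615 and not past the test with genes well above background on all 24 arrays). In the WRKY family 45 of 69 genes rose, 46 when adjusted over the list alone, and 7 fell (median 1.07, adjusted p = 2.31e-09). In the NAC family 37 of 61 rose and 4 fell (median 0.70, adjusted p = 3.04e-07). Of 45 glutathione S-transferases 26 rose and 7 fell (median 1.04, adjusted p = 0.000108, or adjusted p = 0.0903 with an estimated correlation). Of 25 genes of the cell cycle and DNA replication 23 fell, and 2 did not pass (median -1.46, adjusted p = 1.76e-06, or adjusted p = 0.192 with an estimated correlation). Of 219 cytosolic ribosomal protein genes 182 fell, 183 when adjusted over the list alone, and 5 rose (median -0.63, adjusted p = 6.98e-13, or adjusted p = 0.155 with an estimated correlation). Of 42 photosynthesis genes 13 fell, 11 when adjusted over the list alone, and 29 did not pass (median -0.26, adjusted p = 0.236, but past the test with normexp background, adjusted p = 8.55e-06).

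In all, 6588 genes rose and 9822 fell in Col-0 at 4 h. The 24 arrays lay on 6 slides of 4 arrays, slides 1 to 3 with arrays labelled med14 alone and slides 4 to 6 with Col-0 alone. Slide 4 held all 3 Col-0 arrays of 0 h and 1 of 4 h, and within it 99.9% of the called genes kept their sign. The same arrays took part in the calls, so this is no separate check on slides. With slide as a fixed block, which at 4 h rests on that slide, 14752 genes were called. The list medians were then 3.07 for SA, 1.13 for the pathogenesis-related genes (adjusted p = 0.065, no longer past the threshold), 2.55 for jasmonate and 2.18 for pattern-triggered immunity. They were 1.89 for camalexin, 2.81 for heat shock, -1.73 for the cell cycle, 2.39 for senescence, -0.43 for photosynthesis, 1.2 for WRKY, 0.95 for NAC, -0.67 for ribosomal proteins and 1.18 for glutathione S-transferases.

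At 8 h in Col-0, SA genes were up and photosynthesis genes down. EDS5 rose by 7.85 ± 0.14, ICS1 by 5.26 ± 0.14 and PBS3, which joins glutamate to the SA precursor, by 9.43 ± 0.17. PR1 rose at least 50.4-fold, PR2 by 5.29 ± 0.42, WRKY38 by 6.19 ± 0.27, and FMO1, which makes N-hydroxypipecolic acid, at least 479-fold, while PR5 had a change of -0.06 ± 0.20 that did not pass (adjusted p = 0.8). PAD3 (at least 3080-fold) and BAP2 (at least 3170-fold) were measured on no array of 0 h. EXPA8 fell at least 373-fold and was still measured on 2 of the 3 arrays of 8 h. Of the 32 SA and pipecolate genes 31 rose and 1 did not pass (median 4.98, adjusted p = 1.26e-15, or adjusted p = 0.0844 with an estimated correlation). All 19 genes of protein folding and secretion in the endoplasmic reticulum rose (median 1.68, adjusted p = 2.3e-08, or adjusted p = 0.155 with an estimated correlation), including the chaperone BIP1 (2.40 ± 0.11). Of 42 photosynthesis genes 37 fell and 5 did not pass (median -1.03, adjusted p = 0.000125, or adjusted p = 0.501 with an estimated correlation). Of 10 morning clock genes 9 fell, among them LNK2 (by 2.87 ± 0.12), and 1 did not pass (median -1.32, adjusted p = 0.00414, or adjusted p = 0.119 with an estimated correlation). In all 8159 genes rose and 10755 fell. No slide held arrays of both 8 h and 0 h, and a slide block left 15932 genes called. Its medians were 5.27 for SA, 1.78 for the endoplasmic reticulum, -1.12 for photosynthesis and -1.43 for the morning clock genes.

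At 12 h in Col-0, all photosynthesis genes had fallen. PR1 rose at least 734-fold, FMO1 at least 1160-fold and PAD3 at least 3820-fold. ICS1 (4.12 ± 0.14) and EDS5 (6.74 ± 0.14) were still up, and PR5 rose by 0.53 ± 0.20 with overlapping arrays (adjusted p = 0.0239). The PR5 call was lost without 0 h replicate 2 (adjusted p = 0.0624) or 3 (adjusted p = 0.0857), without 12 h replicate 1 (adjusted p = 0.064) or 2 (adjusted p = 0.124) and with slide as a fixed block (0.72, adjusted p = 0.145). All 42 photosynthesis genes fell (median -2.52, adjusted p = 9.88e-10, or adjusted p = 0.363 with an estimated correlation), the light-harvesting gene LHCB4.2 by 5.69 ± 0.23. All 10 genes of aliphatic glucosinolate synthesis fell (median -4.27, adjusted p = 0.00155, or adjusted p = 0.36 with an estimated correlation), including the regulator MYB28 (by 4.02 ± 0.23). Of 11 auxin response genes 8 fell, such as IAA3 (by 5.81 ± 0.18), and 3 rose (median -2.63, adjusted p = 0.0406, or adjusted p = 0.205 with an estimated correlation).

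Clock genes at 12 h in Col-0 went both ways. Of 10 morning genes 9 fell and 1 did not pass (median -3.72, adjusted p = 0.00076, or adjusted p = 0.131 with an estimated correlation). LNK2 fell by 4.87 ± 0.12, LNK1 by 4.05 ± 0.10, CCA1 by 3.39 ± 0.12, LHY by 2.04 ± 0.13 and PRR9 at least 15.6-fold (the last 2 lost with normexp background, adjusted p = 0.603 and 0.822). Of 11 day and evening genes 7 fell, 8 when adjusted over the list alone, and 3 rose (median -0.39, adjusted p = 0.221). PRR7 fell by 4.71 ± 0.09, GI by 4.63 ± 0.15, CHE by 4.29 ± 0.15, PRR5 by 2.90 ± 0.11 and LUX by 0.87 ± 0.09. BOA rose by 4.40 ± 0.21, ELF4 by 3.53 ± 0.11 and TOC1 by 1.13 ± 0.09. The source names of these 3 samples give another time, 24 h, while titles, characteristics and design give 12 h, which was used. In all 8994 genes rose and 10598 fell at 12 h. The fixed slide block called 14995 genes. Its medians were -2.25 for photosynthesis, -4.41 for aliphatic glucosinolates, -2.82 for auxin, -3.74 for morning and -0.39 for evening clock genes.

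**Figure D2:**
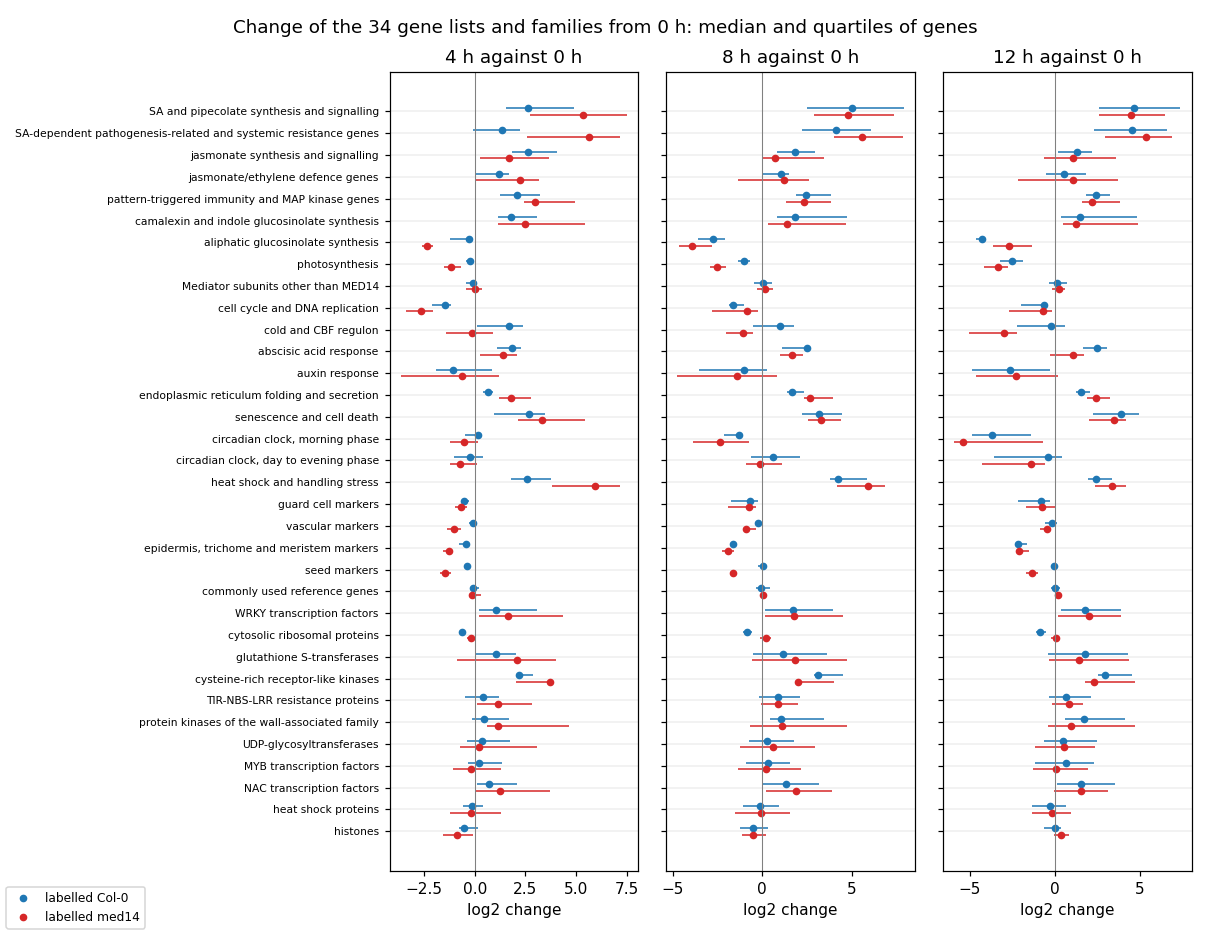
Median log2 change from 0 h (points) with quartiles of the genes (lines) for the 34 gene lists and families at 4, 8 and 12 h, blue for arrays labelled Col-0 and red for arrays labelled med14. The median of the SA list at 4 h is 2.64 in Col-0 and 5.33 in med14, and that of photosynthesis at 12 h is -2.52 and -3.37.

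The response of the mutant was read in the same way. In leaves labelled med14 SA genes were up at 4 h. ICS1 rose by 6.40 ± 0.14, EDS5 by 7.67 ± 0.14, WRKY38 by 5.53 ± 0.27, PR2 by 4.33 ± 0.42 and NPR1, the SA receptor, by 2.46 ± 0.08. PR1 rose at least 80.9-fold, FMO1 at least 2660-fold and ALD1, the first enzyme of pipecolate synthesis, at least 672-fold, none of them measured at 0 h, and PAD3, measured on 2 arrays of 0 h, at least 5010-fold. ORA59, a regulator of jasmonate and ethylene defence, rose by 2.03 ± 0.45 (adjusted p = 0.000466, but 0.313 with normexp background), while the defensin gene PDF1.2a had a change of -0.66 ± 0.74 (adjusted p = 0.43, but -0.53 and past the test with the authors' values, adjusted p = 0.0461). GASA6 fell by 7.57 ± 0.59.

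Of the 32 SA and pipecolate genes 31 rose and 1 fell at 4 h in med14 (median 5.33, adjusted p = 1.39e-16, or adjusted p = 0.0592 with an estimated correlation). Of 10 pathogenesis-related genes 9 rose and 1 did not pass, including PNP-A (6.98 ± 0.21) and AZI1 (at least 82.4-fold) (median 5.65, adjusted p = 6.92e-05, or adjusted p = 0.0638 with an estimated correlation). Of 24 genes of pattern-triggered immunity 22 rose, among them MPK11 (8.43 ± 0.19) and the MAP kinase kinase MKK4 (5.50 ± 0.14), and 2 did not pass (median 2.95, adjusted p = 7.32e-12, or adjusted p = 0.0592 with an estimated correlation). Of 42 photosynthesis genes 36 fell and 6 did not pass (median -1.17, adjusted p = 0.000141, or adjusted p = 0.544 with an estimated correlation). Of 25 cell cycle genes 22 fell and 1 rose (median -2.67, adjusted p = 2.99e-05, or adjusted p = 0.296 with an estimated correlation), MCM7 by 4.04 ± 0.15. All 8 vascular markers fell (median -1.04, adjusted p = 0.0456, or adjusted p = 0.357 with an estimated correlation). That call was also lost without med14 0 h replicate 1 (adjusted p = 0.0548) or 3 (adjusted p = 0.0561) or 4 h replicate 1 (adjusted p = 0.0576). Of 41 histone genes 25 fell and 4 rose (median -0.89, adjusted p = 0.0153, or adjusted p = 0.529 with an estimated correlation). The 219 ribosomal protein genes were mixed, 95 down (91 when adjusted over the list alone) and 32 up (median -0.19, adjusted p = 0.475). In all 7613 genes rose and 11295 fell. Slide 1 held all 3 med14 arrays of 0 h and 1 of 4 h, and within it 99.8% of the called genes kept their sign. The fixed slide block called 16399 genes. Medians were then 4.90 for SA, 4.49 for pathogenesis-related genes, 3.00 for pattern-triggered immunity, -0.97 for photosynthesis, -2.53 for the cell cycle, -0.92 for vascular markers (adjusted p = 0.0601, no longer past the threshold), -0.90 for histones and -0.15 for ribosomal proteins.

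At 8 h in med14, protein folding genes were up and photosynthesis genes down. PR1 rose at least 982-fold, FMO1 at least 3470-fold, PAD3 at least 3900-fold, and ARD3, an enzyme of the methionine salvage cycle, at least 6110-fold. PR5 rose by 2.05 ± 0.20, ICS1 by 5.26 ± 0.14 and ORA59 by 2.37 ± 0.45, while the defensin genes PDF1.2a (by 2.07 ± 0.74, adjusted p = 0.0154) and PDF1.2b (by 2.42 ± 0.45) fell. The PDF1.2a call was lost without 0 h replicate 2 (adjusted p = 0.0648) or 8 h replicate 3 (adjusted p = 0.0645), and both calls with slide as a fixed block (-1.27 and -1.83, adjusted p = 0.49 and 0.0777). Normexp background ended the calls of ORA59, PDF1.2a and PDF1.2b (adjusted p = 0.379, 0.0787 and 0.0511). All 19 genes of the endoplasmic reticulum rose (median 2.66, adjusted p = 9.82e-10, or adjusted p = 0.14 with an estimated correlation), BIP2 by 4.71 ± 0.13 and BIP1 by 4.24 ± 0.11. All 42 photosynthesis genes fell (median -2.55, adjusted p = 3.23e-09, or adjusted p = 0.377 with an estimated correlation), PRK by 3.88 ± 0.15. Of 10 morning clock genes 8 fell, such as CCA1 (by 4.15 ± 0.12), and 1 rose (median -2.34, adjusted p = 0.00987, or adjusted p = 0.14 with an estimated correlation). In all 8920 genes rose and 11245 fell. Slide as a fixed block left 15382 genes called. Medians under it were 2.45 for the endoplasmic reticulum, -2.28 for photosynthesis and -2.59 for the morning clock genes, and no slide held arrays of both times.

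At 12 h in med14, light-harvesting and cold-response genes were below their level at 0 h. LHCB2.3 fell by 10.53 ± 0.38, LHCB4.2 by 7.00 ± 0.23 and PSAL by 3.97 ± 0.14, and all 42 photosynthesis genes fell (median -3.37, adjusted p = 2.53e-13, or adjusted p = 0.284 with an estimated correlation). Of 15 cold and CBF regulon genes 13 fell, such as COR15B (by 5.01 ± 0.22) and CBF3 (at least 101-fold), and 2 rose (median -3.01, adjusted p = 0.00129, or adjusted p = 0.179 with an estimated correlation). PR1 rose at least 1970-fold, FMO1 at least 2840-fold, PR5 by 2.60 ± 0.20 and ORA59 by 3.75 ± 0.45. PDF1.2a fell by 3.42 ± 0.74 (adjusted p = 0.000364) and PDF1.2b by 3.41 ± 0.45, calls that were lost with slide as a fixed block (-1.91 and -2.40, adjusted p = 0.43 and 0.0754). Of 10 morning clock genes 8 fell and 2 did not pass (median -5.42, adjusted p = 0.000483, or adjusted p = 0.12 with an estimated correlation), LNK1 by 5.97 ± 0.10 and CCA1 at least 48-fold. Of 11 day and evening genes 8 fell and 2 rose (median -1.40, adjusted p = 0.00501, or adjusted p = 0.177 with an estimated correlation). GI fell by 6.24 ± 0.15, PRR7 by 6.21 ± 0.09, PRR5 by 4.70 ± 0.11 and LUX by 3.09 ± 0.09. BOA rose by 3.71 ± 0.21 and ELF4 by 0.45 ± 0.11, and TOC1 had a change of -0.06 (adjusted p = 0.522). In all 8951 genes rose and 10313 fell. With slide as a fixed block the count was 12728, more than 1.5 times lower. The medians were -3.47 for photosynthesis, -3.19 for cold, -4.88 for morning and -1.26 for evening clock genes.

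The genotypes were then compared at each time. At 0 h several jasmonate and ethylene defence transcripts were higher on arrays labelled med14. PDF1.2a was at least 37.5-fold higher (measured on 1 of 3 Col-0 arrays), PDF1.2b at least 39-fold and ORA59 at least 4.27-fold. The log2 difference of ORA59 was 0.22 with the authors' values (adjusted p = 0.101) and 1.59 with normexp background (adjusted p = 0.243). PR4, a chitin-binding protein gene near MED14 by locus number, was higher by 3.65 ± 0.23 (adjusted p = 3.92e-09). A local effect of the mutation on PR4 was not tested. ICS1 was lower (-0.69 ± 0.14, adjusted p = 0.0012, but 0.265 with normexp background), while PR2 (0.06, adjusted p = 0.937) did not pass and PR1 and FMO1 were at background with both labels. EXLB1, an expansin-like gene, was higher (5.71 ± 0.29), the lipid transfer protein genes LTP4 (-5.90 ± 0.67) and LTP3 (-4.68 ± 0.61) lower.

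Of 14 jasmonate and ethylene defence genes at 0 h, 8 were higher and 1 lower on arrays labelled med14 (median 0.83, adjusted p = 0.00307, or adjusted p = 0.29 with an estimated correlation). Of 27 genes of jasmonate synthesis and signalling 12 were lower, 13 when adjusted over the list alone, such as MYC2 (-0.87 ± 0.12), and none higher (median -0.50, adjusted p = 0.00428, or adjusted p = 0.699 with an estimated correlation). Without Col-0 replicate 3 this call was lost (adjusted p = 0.0795). Of 15 cold and CBF genes 8 were higher, among them RD29A (3.46 ± 0.19), and 1 lower (median 0.52, adjusted p = 6.2e-05, or adjusted p = 0.215 with an estimated correlation). Of 219 ribosomal protein genes 180 were lower, 187 when adjusted over the list alone, and 1 higher, with RPL5B at -0.80 ± 0.07 (median -0.51, adjusted p = 1.55e-28, or adjusted p = 0.137 with an estimated correlation). Of 19 genes of the endoplasmic reticulum 14 were lower and 2 higher, BIP2 at -1.49 ± 0.13 (median -0.52, adjusted p = 1.24e-05, or adjusted p = 0.495 with an estimated correlation). Of 10 morning clock genes 5 were lower and none higher (median -0.46, adjusted p = 0.00307, or adjusted p = 0.146 with an estimated correlation). Of 11 day and evening genes 7 were higher, ELF4 by 1.89 ± 0.11, and none lower (median 0.73, adjusted p = 2.41e-06, or adjusted p = 0.0959 with an estimated correlation). In the SA and pipecolate list 14 of 32 genes were higher, such as WRKY18 (1.08 ± 0.11), and 5 lower (median 0.24, adjusted p = 0.061). The list passed without 1 of 3 arrays, med14 replicate 1 (adjusted p = 0.00752) or 3 (adjusted p = 0.0417) or Col-0 replicate 3 (adjusted p = 0.0358), with normexp background (0.000791), without a filter (0.0448), with an intensity trend (0.0483) and with genes well above background on all 24 arrays (0.00566).

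Further lists did not pass at 0 h. Of 33 Mediator subunits other than MED14, 4 were higher and 5 lower (median -0.13, or 0.03 with normexp background, adjusted p = 0.366). Of 12 commonly used reference genes 6 were lower, EF1A at -0.93 ± 0.16, and none higher, 1 when adjusted over the list alone (median -0.25, adjusted p = 0.12), but the list passed with normexp background (adjusted p = 0.000272), the authors' values (0.0465), no filter (0.0448) or the mean of all probes (0.0322). Neither of 2 seed markers passed (median 0.26 with a test direction of lower, adjusted p = 0.979). The direction of their test turned under normexp, with or without one background per array, with the mean of all probes, with the arrays compared alone and without 1 of 3 arrays (med14 replicates 1 and 2 and Col-0 replicate 1). In all 4516 genes were higher and 4955 lower on arrays labelled med14. Since each slide held 1 genotype, slide could enter these comparisons only as a random block, which gave 5838 genes at 0 h, more than 1.5 times fewer. It gave medians of 0.80 for jasmonate and ethylene defence, -0.46 for jasmonate, 0.49 for cold, -0.52 for ribosomal proteins, -0.45 for the endoplasmic reticulum and -0.51 and 0.71 for morning and evening clock genes. Of lists not past the test, it gave -0.10 for Mediator, -0.22 for reference genes, -0.04 for seed markers and 0.33 for SA (adjusted p = 0.00292).

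At 4 h SA and defence genes were higher on arrays labelled med14. FMO1 was higher by 10.08 ± 0.47 (adjusted p = 6.1e-12), PAD3 by 7.75 ± 0.19 (adjusted p = 7.46e-15), WRKY38 by 4.74 ± 0.27, ICS1 by 2.91 ± 0.14, PR2 by 2.78 ± 0.42, PR5 by 1.65 ± 0.20 and NPR1 by 1.35 ± 0.08, and PR1 was at least 81.5-fold higher. PDF1.2a (at least 42.6-fold), PDF1.2b (at least 21.2-fold) and ORA59 (at least 19.1-fold) were higher too, the last 2 not past the test with normexp background (adjusted p = 0.105 and 0.17). PCR1, a plasma membrane protein of cadmium resistance, was at least 1340-fold higher and ARD3 at least 641-fold, each measured on 1 of 3 Col-0 arrays.

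Of 32 SA and pipecolate genes 29 were higher at 4 h and 1 lower, including EDS1 (2.74 ± 0.10) (median 1.92, adjusted p = 1.05e-13, or adjusted p = 0.0923 with an estimated correlation). Of 10 pathogenesis-related genes 9 were higher, such as PNP-A (5.56 ± 0.21), and none lower (median 2.22, adjusted p = 9.88e-05, or adjusted p = 0.0923 with an estimated correlation). Of 14 jasmonate and ethylene defence genes 13 were higher, PR4 by 4.24 ± 0.23, and none lower (median 2.56, adjusted p = 2.08e-06, or adjusted p = 0.0923 with an estimated correlation). Of 27 genes of jasmonate synthesis and signalling 21 were lower, such as AOC4 (-2.11 ± 0.13), and none higher (median -1.43, adjusted p = 1.62e-05, or adjusted p = 0.275 with an estimated correlation). Of 24 genes of pattern-triggered immunity 21 were higher, among them MKK4 (2.45 ± 0.14), and 2 lower (median 1.2, adjusted p = 2.24e-07, or adjusted p = 0.148 with an estimated correlation). Of 59 TIR-NBS-LRR resistance genes 46 were higher and 1 lower, AT4G11170 by 4.56 ± 0.21 (median 0.88, adjusted p = 4.85e-12, or adjusted p = 0.0923 with an estimated correlation). All 5 cysteine-rich receptor-like kinases were higher, CRK5 by 1.37 ± 0.11 (median 1.16, adjusted p = 0.00608, or adjusted p = 0.173 with an estimated correlation). So were 7 of 11 wall-associated kinases, WAK1 by 3.80 ± 0.24, with 1 lower (median 2.13, adjusted p = 0.00196, or adjusted p = 0.148 with an estimated correlation).

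Photosynthesis genes were lower on arrays labelled med14 at 4 h, 41 of 42, with GAPA at -1.51 ± 0.14 and PSBO2 at -1.37 ± 0.12 (median -1.0, adjusted p = 1.07e-06, or adjusted p = 0.455 with an estimated correlation). All 5 epidermis, trichome and meristem markers were lower, ATML1, a regulator of epidermal identity, by a difference of -0.67 ± 0.11 (0.02 with the authors' values, adjusted p = 0.711), without the list passing (median -0.95, or 0.24 with normexp background, adjusted p = 0.0776, or 0.0274 with the arrays compared alone). Of 91 heat shock proteins 32 were higher, 33 when adjusted over the list alone and 34 lower (median 0.03, or -0.07 with normexp and one background per array and -0.01 with the mean of all probes, adjusted p = 0.589). In all 6984 genes were higher and 9035 lower. Slide as a random block left 14480 genes called. The medians under it were 1.89 for SA, 2.14 for pathogenesis-related genes, 2.58 for jasmonate and ethylene defence, -1.43 for jasmonate, 1.19 for pattern-triggered immunity. They were -0.88 for photosynthesis, -0.91 for the epidermis, 0.84, 1.23 and 2.12 for the TIR-NBS-LRR, cysteine-rich and wall-associated families and -0.01 for heat shock proteins.

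At 8 h some SA marker genes were higher and some lower on arrays labelled med14, and photosynthesis genes were lower. PR1 (4.28 ± 0.69, adjusted p = 3.54e-05) and FMO1 (2.89 ± 0.47) were higher, ICS1 (-0.68 ± 0.14, adjusted p = 0.000556) was lower, and PR2 (-0.07, adjusted p = 0.888) did not pass. ORA59 was at least 24.1-fold and PDF1.2a at least 17.1-fold higher (adjusted p = 0.0748 and 0.14 with normexp background). Of 32 SA and pipecolate genes 15 were higher, such as EPS1 (2.00 ± 0.20), which releases SA from the glutamate conjugate of its precursor, and 3 lower (median 0.42, adjusted p = 0.0882). The list did pass with normexp background (adjusted p = 0.00508, or 0.00746 with one per array), quantile normalization (0.0212), the authors' values (0.0262), no filter (0.0159) and the arrays compared alone (0.019). Of 14 jasmonate and ethylene defence genes 10 were higher, PR4 by 2.30 ± 0.23, and 2 lower (median 1.36, adjusted p = 0.0136, or adjusted p = 0.558 with an estimated correlation). All 42 photosynthesis genes were lower, GAPA at -1.77 ± 0.14 (median -1.60, adjusted p = 5.02e-14, or adjusted p = 0.573 with an estimated correlation). Of 219 ribosomal protein genes 169 were higher, 171 when adjusted over the list alone, and 11 lower, 12 when adjusted over the list alone (median 0.54, adjusted p = 1.71e-17, or adjusted p = 0.526 with an estimated correlation), opposite in direction to 0 h. In all 7351 genes were higher and 8400 lower (46.7% higher), while the authors' values gave 7870 and 5806 (57.5% higher), and 2079 and 4336 differed by at least 2-fold (32.4% higher). Slide as a random block left 13726 genes called. List medians with it were 0.34 for SA, 1.34 for jasmonate and ethylene defence, -1.5 for photosynthesis and 0.54 for ribosomal proteins.

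At 12 h glucosinolate and ethylene defence genes were higher on arrays labelled med14. PR1 (1.41, adjusted p = 0.0898) and PR2 (-0.23, adjusted p = 0.668) did not pass. PR1 did pass with quantile normalization (1.79, adjusted p = 0.0357), the authors' values (1.55, adjusted p = 0.0116) and the arrays compared alone (adjusted p = 0.00262). PR5 was higher by 2.11 ± 0.20 and ICS1 by 0.47 ± 0.14 (adjusted p = 0.0105, or 0.0897 with slide as a random block). ORA59 was at least 90.3-fold higher, measured on 1 of 3 Col-0 arrays, PDF1.2a at least 9.84-fold (0.52 with the authors' values, adjusted p = 0.0663, and -0.25 with normexp background, adjusted p = 0.837), whereas the thionin gene THI2.2 was at least 90.2-fold lower. All 10 genes of aliphatic glucosinolate synthesis were higher (median 2.17, adjusted p = 0.000118, or adjusted p = 0.436 with an estimated correlation). Of 19 genes of camalexin and indole glucosinolates 12 were higher, 14 when adjusted over the list alone, such as CYP79B3 (1.54 ± 0.18), and none lower (median 0.74, adjusted p = 0.000116, or adjusted p = 0.283 with an estimated correlation). Of 14 jasmonate and ethylene defence genes 12 were higher, ERF5 by 2.76 ± 0.25, and none lower (median 1.24, adjusted p = 0.000238, or adjusted p = 0.262 with an estimated correlation). All 10 abscisic acid response genes were lower, such as RD22 (-2.85 ± 0.23) (median -1.5, adjusted p = 8.63e-06, or adjusted p = 0.262 with an estimated correlation). Of 42 photosynthesis genes 33 were lower and 1 higher, LHCB3 at -2.73 ± 0.24 (median -1.09, adjusted p = 9.24e-09, or adjusted p = 0.671 with an estimated correlation).

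Several lists did not pass at 12 h. In the SA list 7 of 32 genes were higher and 12 lower, 13 when adjusted over the list alone (median -0.29, adjusted p = 0.534). Of 6 guard cell markers 4 were higher (median 0.36, or -0.19 with normexp background, adjusted p = 0.228). Of 107 UDP-glycosyltransferases 21 were higher and 43 lower, 44 when adjusted over the list alone (median -0.31, adjusted p = 0.248). Of 83 MYB genes 29 were higher, MYB4 by 2.19 ± 0.12, and 27 lower, 31 when adjusted over the list alone. They had a median of -0.05, a mean of 0.04 and a test direction of higher (adjusted p = 0.951) that turned under normexp, quantile normalization, the authors' values, with genes well above background on all 24 arrays and without Col-0 replicate 2. In all 6955 genes were higher and 6744 lower on arrays labelled med14. The random slide block called 10968 genes. List medians were then -0.29 for SA, 2.50 for aliphatic and 0.75 for indole glucosinolates, 1.35 for jasmonate and ethylene defence, -1.5 for abscisic acid, -1.19 for photosynthesis, 0.38 for guard cells, -0.34 for UDP-glycosyltransferases and -0.06 for MYB genes.

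The change from 0 h was itself compared between genotypes, as the test of whether the mutant responds otherwise. At 4 h it was larger in med14 for PAD3 (difference of log2 changes 7.08 ± 0.27), FMO1 (9.40 ± 0.67), PR1 (8.15 ± 0.97), WRKY38 (4.31 ± 0.38), ICS1 (3.6 ± 0.20), ORA59 (2.70 ± 0.63), PR2 (2.73 ± 0.60), EDS5 (2.21 ± 0.20), PR5 (1.61 ± 0.29), NPR1 (1.32 ± 0.11) and WRKY70 (1.06 ± 0.19). It did not pass for PDF1.2a (0.94 ± 1.04, adjusted p = 0.47). PR1 and FMO1 were at background in both genotypes at 0 h, PAD3 and ORA59 in Col-0 at 0 h, and PR1 and ORA59 in Col-0 also at 4 h, so for these the value is the fitted one and no bound. With normexp background the differences of PR1 (1.86, adjusted p = 0.45) and ORA59 (0.07, adjusted p = 0.993) did not pass. Of 32 SA and pipecolate genes 27 had a more positive change in med14, EDS1 by 2.87 ± 0.14, and 1 a more negative one, 2 when adjusted over the list alone (median 1.55, adjusted p = 2.07e-12, or adjusted p = 0.187 with an estimated correlation). The same held for 9 of 10 pathogenesis-related genes, PNP-A by 4.59 ± 0.29 (median 2.64, adjusted p = 2.07e-05, or adjusted p = 0.187 with an estimated correlation). It held for 18 of 24 genes of pattern-triggered immunity, 20 when adjusted over the list alone, MKK4 by 2.61 ± 0.19 (median 1.28, adjusted p = 1.2e-06, or adjusted p = 0.216 with an estimated correlation). It also held for 17 of 19 genes of the endoplasmic reticulum, BIP2 by 2.42 ± 0.18 (median 1.16, adjusted p = 3.9e-09, or adjusted p = 0.216 with an estimated correlation). Of 219 ribosomal protein genes 139, or 141 when adjusted over the list alone, had a more positive change (median 0.48, adjusted p = 1.04e-13, or adjusted p = 0.216 with an estimated correlation). Of 42 photosynthesis genes 24, or 25 when adjusted over the list alone, had a more negative one, PSBO2 by -1.14 ± 0.18 (median -0.85, adjusted p = 2.07e-05, or adjusted p = 0.478 with an estimated correlation). Of 11 genes of heat shock and handling stress 8 changed more positively and 1 more negatively (median 2.12, or -0.26 with normexp background, adjusted p = 0.000179, or adjusted p = 0.187 with an estimated correlation), with changes from 0 h of 5.56 in med14 and 2.81 in Col-0 within slides 1 and 4. In all 5930 genes had a more positive and 7080 a more negative change. With slide as a fixed block the count fell by more than 1.5 times to 7341. Medians became 1.15 for SA, 1.64 for pathogenesis-related genes, 0.89 for pattern-triggered immunity, 0.93 for the endoplasmic reticulum, 0.55 for ribosomal proteins, -0.49 for photosynthesis and 1.62 for heat shock. The calls of ORA59 (1.54, adjusted p = 0.111) and PR2 (1.40, adjusted p = 0.185) were lost.

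At 8 h the changes of ICS1 (difference 0.00 ± 0.20, adjusted p = 0.992) and PAD3 (0.19, adjusted p = 0.579) did not differ past the test. ICS1 passed with slide as a fixed block (-1.06, adjusted p = 0.0101), where PAD3 was at -0.50, and PAD3 passed with the authors' values (adjusted p = 6.31e-05) and with normexp and one background per array (0.84, adjusted p = 0.00191). PR1 (5.20 ± 0.97), PR5 (2.11 ± 0.29), FMO1 (2.21 ± 0.67, adjusted p = 0.0116) and ORA59 (3.18 ± 0.63) changed more positively in med14, and PDF1.2b (-3.80 ± 0.64) more negatively. Except for PR5 these are fitted values and no bounds, since PR1 and FMO1 were at background at 0 h, ORA59 in Col-0 at 0 and 8 h, and PDF1.2b in Col-0 at 0 h and on 2 of 3 arrays of 8 h. Of 32 SA and pipecolate genes 6 changed more positively and 6 more negatively (median 0.19, or -0.14 with normexp background, adjusted p = 0.838), but with slide as a fixed block the median was -0.65 and the list passed (adjusted p = 0.00365). Its direction also turned without med14 0 h replicate 1 (adjusted p = 0.974). Of 42 photosynthesis genes 38 changed more negatively, 39 when adjusted over the list alone (median -1.38, adjusted p = 3.17e-12, or adjusted p = 0.513 with an estimated correlation). Of 219 ribosomal protein genes 194 changed more positively, 195 when adjusted over the list alone (median 1.05, adjusted p = 1.07e-41, or adjusted p = 0.0714 with an estimated correlation). In all 5589 genes changed more positively and 6336 more negatively (46.9% positive, but 54.6% with the authors' values). The slide block left 3794 genes, more than 1.5 times fewer. It gave medians of -1.08 for photosynthesis and 1.08 for ribosomal proteins. It ended the calls of PR1 (0.80, adjusted p = 0.694), PR5 (1.18, adjusted p = 0.0987), FMO1 (0.22, adjusted p = 0.925), ORA59 (1.75, adjusted p = 0.218) and PDF1.2b (-2.11, adjusted p = 0.265). Normexp background ended the same calls except that of PR5 (adjusted p = 0.131, 0.334, 0.767 and 0.126).

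At 12 h cold and evening clock genes changed more negatively in med14. Of 15 cold genes 13 did so, RD29A by -4.26 ± 0.27, and 1 more positively (median -2.35, adjusted p = 1.25e-07, or adjusted p = 0.066 with an estimated correlation). Of 11 day and evening clock genes 9, or 10 when adjusted over the list alone, changed more negatively, such as ELF4 (-3.08 ± 0.15) and LUX (-2.21 ± 0.12), and none more positively (median -1.2, adjusted p = 1.92e-07, or adjusted p = 0.0562 with an estimated correlation). Of 219 ribosomal protein genes 186 changed more positively, 191 when adjusted over the list alone, and 2 more negatively (median 0.83, adjusted p = 1.78e-33, or adjusted p = 0.066 with an estimated correlation). In the SA list 3 of 32 genes changed more positively and 13 more negatively, 14 when adjusted over the list alone (median -0.38, adjusted p = 0.0565), and the list passed with slide as a fixed block (median -1.19, adjusted p = 3.38e-05). It also passed without any 1 of 5 arrays, with adjusted p = 0.0112 and 0.0463 without med14 0 h replicates 1 and 3, 0.046 without med14 12 h replicate 1, 0.0407 without Col-0 0 h replicate 3 and 0.0415 without Col-0 12 h replicate 3. Other settings where it passed were normexp with one background per array (adjusted p = 0.0272), no filter (0.0142), genes well above background on all 24 arrays (0.0235), the mean of all probes (0.0305) and an intensity trend (0.0486). PR5 (2.07 ± 0.29), ICS1 (1.16 ± 0.20) and ORA59 (4.02 ± 0.63) changed more positively, PDF1.2b (-5.04 ± 0.64) more negatively. The values of ORA59 (at background in Col-0 at 0 h and on 2 of 3 arrays of 12 h, and 0.93 with normexp background, adjusted p = 0.528) and PDF1.2b (at background in Col-0 at 0 h) are fitted and no bounds. PR1 did not pass (2.34, adjusted p = 0.06). It did without med14 0 h replicate 1 (adjusted p = 0.0429) or Col-0 0 h replicate 2 (0.04). So it did with quantile normalization (0.0312), an intensity trend (0.0473) or the arrays compared alone (0.00733). PR1 turned to -2.58 with slide as a fixed block. In all 5687 genes changed more positively and 5284 more negatively. Slide as a fixed block left 3666, more than 1.5 times fewer. Medians were then -2.60 for cold, -1.01 for evening clock and 0.75 for ribosomal protein genes. The calls of PR5 (1.15, adjusted p = 0.198), ICS1 (-0.12, adjusted p = 0.823), ORA59 (3.20, adjusted p = 0.0757) and PDF1.2b (-2.52, adjusted p = 0.287) ended.

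Across all 25230 genes tested, the slope of the major axis of the change in med14 against that in Col-0 was 1.57 at 4 h (1.5 to 1.67 leaving out each array, jackknife SE 0.137). It was 1.2 at 8 h (1.16 to 1.23, SE 0.048) and 0.97 at 12 h (0.95 to 0.99, SE 0.028). Within 1 slide per genotype at 4 h, the slope was 1.34 (1.28 to 1.39, SE 0.07).

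**Figure D3:**
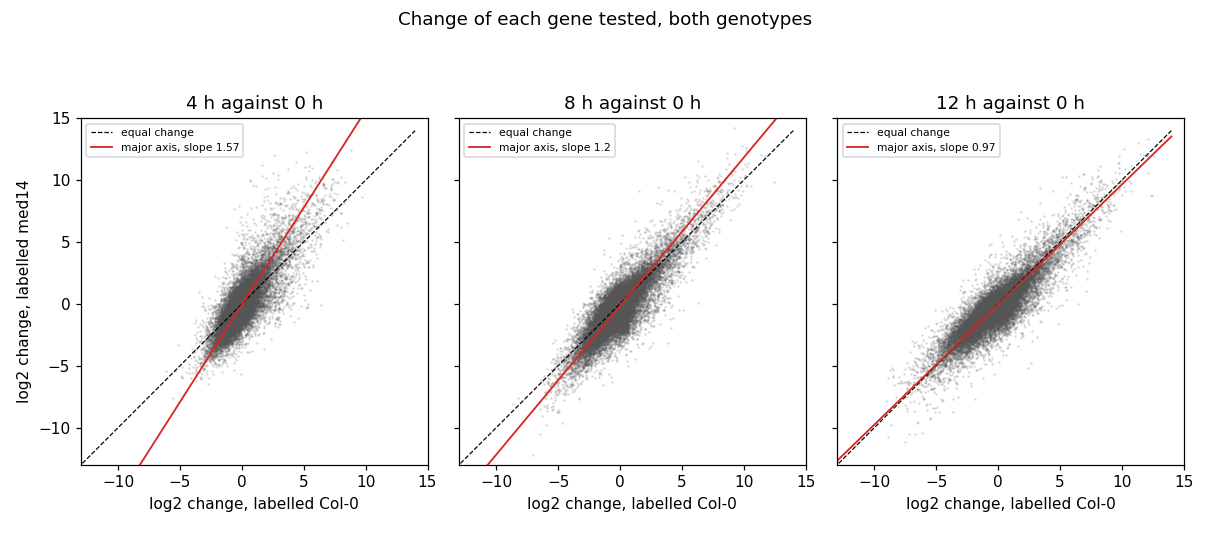
Log2 change from 0 h of each of the 25230 genes tested (points) on arrays labelled Col-0 (x axis) and med14 (y axis) at 4, 8 and 12 h, with the line of equal change (dashed) and the major axis (red). The slope is 1.57 at 4 h and 0.97 at 12 h.

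The genes called between genotypes were compared between times. At 4 and 8 h 3975 genes were higher on arrays labelled med14 at both times where 2035 would be expected from the number at each (1.95 times), and 5326 lower where 3008 would be expected (1.77 times). At 8 and 12 h 4064 were higher (2.01 times the expected 2026) and 4136 lower (1.84 times the expected 2245), and at 4 and 12 h 2374 (1.23 times 1925) and 3006 (1.24 times 2415). The 0 h calls shared 2137 higher (1.71 times 1250) and 2514 lower genes (1.42 times 1774) with 4 h, 2186 (1.66 times 1316) and 2102 (1.27 times 1650) with 8 h, and 2058 (1.65 times 1245) and 1711 (1.29 times 1324) with 12 h. At all 4 times 827 genes were higher and 981 lower. These 4 comparisons share no array, but neighbouring times share slides, an effect that the expected numbers leave out. With slide as a random block, 4 overlaps with 0 h were over 1.5 times smaller, down to 1210 higher (1.90 times the 637 expected with that block) and 971 lower genes (1.54 times 632) at 12 h.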

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

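The tests of MED14 and of Col-0 0 h replicate 3 were chosen only after the result was seen. The results in this part drew attention because the change from 0 h differed between arrays labelled med14 and Col-0, by the test of that difference. At 4 h 13010 genes differed in this way. The differences (med14 minus Col-0, log2) were -6.44 for MED14, 8.15 for PR1, 2.73 for PR2, 1.61 for PR5, 3.6 for ICS1, 2.21 for EDS5, 1.32 for NPR1, 4.31 for WRKY38, 1.06 for WRKY70, 9.40 for FMO1, 2.70 for ORA59 and 7.08 for PAD3. The list medians were 1.55 for SA and pipecolate, 2.64 for SA-dependent pathogenesis-related genes, 1.28 for pattern-triggered immunity, 1.16 for the endoplasmic reticulum, 0.48 for ribosomal proteins, 2.12 for heat shock and handling stress and -0.85 for photosynthesis, none past the test with an estimated correlation (adjusted p from 0.187 to 0.478). Slide as a fixed block gave 7341 genes and ended the calls of PR2 and ORA59, and normexp background those of PR1 and ORA59.

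At 8 h 11925 genes differed, MED14 by -6.28, PR1 by 5.20, PR5 by 2.11, FMO1 by 2.21, ORA59 by 3.18, PDF1.2b by -3.80 and EDS5 by -1.03 (-0.51 with the authors' values, adjusted p = 0.0552), with medians of -1.38 for photosynthesis and 1.05 for ribosomal proteins (adjusted p = 0.513 and 0.0714 with an estimated correlation). Slide as a fixed block gave 3794 genes and ended the calls of PR1, PR5, FMO1, ORA59 and PDF1.2b (adjusted p from 0.0987 to 0.925).

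At 12 h 10971 genes differed, MED14 by -6.47, PR5 by 2.07, ICS1 by 1.16, ORA59 by 4.02 and PDF1.2b by -5.04, with medians of -2.35 for cold, -1.2 for evening clock and 0.83 for ribosomal protein genes (adjusted p = 0.066, 0.0562 and 0.066 with an estimated correlation). Slide as a fixed block gave 3666 genes and ended the calls of PR5, ICS1 (then -0.12), ORA59 and PDF1.2b (adjusted p from 0.0757 to 0.823). WRKY38 (-1.08, adjusted p = 0.0294), WRKY70 (-0.52, adjusted p = 0.0365) and NPR1 (-0.31, adjusted p = 0.0304) changed more negatively in med14, and each of these calls was lost without any 1 of 6 arrays. For WRKY38 the adjusted p rose to 0.0849 without med14 0 h replicate 2, 0.0516 without med14 12 h replicate 1, 0.0829 and 0.0696 without Col-0 0 h replicates 2 and 3, and 0.0531 and 0.0668 without Col-0 12 h replicates 1 and 2. For WRKY70 it rose to 0.108 without med14 0 h replicate 2, 0.0637 and 0.0971 without med14 12 h replicates 1 and 2, 0.107 without Col-0 0 h replicate 3, and 0.072 and 0.0633 without Col-0 12 h replicates 1 and 3. For NPR1 it rose to 0.0618 without med14 0 h replicate 2 or 3, 0.0602 and 0.0649 without med14 12 h replicates 1 and 2, 0.0666 without Col-0 0 h replicate 1 and 0.0672 without Col-0 12 h replicate 2. None of these 3 passed with the slide block (adjusted p = 0.0701, 0.112 and 0.117), the authors' values (0.0508, 0.937 and 0.248) or normexp (0.143, 0.923 and 0.539). WRKY70 and NPR1 were lost with quantile normalization (0.162 and 0.102) and one background per array (0.412 and 0.0775), WRKY70 without a filter (0.0522) and with the arrays compared alone (0.0577), and WRKY38 with the mean of all probes (0.0555).

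MED14 was highest on arrays labelled Col-0 at 4 to 12 h. Of those of 0 h, 2 (-4.28 and -2.33) lay below and 1 (-0.47) above all arrays labelled med14. The tables argue against an exchange of the genotype labels of the 0 h arrays alone, since 1808 of the 2268 genes called at all 4 times with one direction at 4, 8 and 12 h kept it at 0 h (79.7%, and 79.6 to 81.4% leaving out each array of 0 h). They also argue against a rise of many Mediator genes in Col-0, since the other 33 subunits had a median change of -0.10 at 4 h (-0.98 to 1.05). An exchange of the labels of all 24 arrays stays open, since MED14 had an SD of 0.1 over the 12 arrays labelled med14 and a range of 8.59 over those labelled Col-0, and a transcript made at an insertion could give that steady level as well. A change of MED14 with infection, infiltration or time of day in Col-0 also stays open and was not tested, so the directions between genotypes rest on the labels.

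By the slope across genes, 1.57 (lower with normexp), changes from 0 h to 4 h were larger in med14, but not for every list. The tables argue against an aberrant Col-0 0 h replicate 3 as the cause, since the slope without it was 1.5. Differences between slides stay open, because slides are nested in genotype and the slope within 1 slide per genotype, 1.34 (1.28 to 1.39), was not above the bound set for it by more than its spread. A stronger or earlier response in the mutant may explain the larger changes and was not tested apart from these.

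The source names of the 3 Col-0 samples of 12 h give 24 h. Leaves taken at 24 h would have been at the time of day of 0 h, and the tables argue against it. Over 21 clock genes the median absolute change from 0 h was 3.39 in Col-0 at 12 h and 3.71 in med14, a ratio of 0.91 (0.88 to 1.01 leaving out each array). A time other than 12 or 24 h stays open.

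Other splits of the arrays were tried for each count of genes. For the difference of changes 100 splits were drawn. At 4 h (13010 genes, highest other 12152) and 12 h (10971, highest other 8509) only the real one of those drawn gave as many. At 8 h 2 of 100 did (11925, highest of the rest 10518). The other exchanged all genotype labels of one time (14647 genes), which turns a difference of genotype effects into their sum. No split drawn at 4 or 12 h held such an exchange, so whether it would give as many there is not known. Few splits thus gave such counts, but they cannot tell genotype from slide, since each slide holds 1 genotype. Slide as a fixed block gave 7341, 3794 and 3666 genes at 4, 8 and 12 h. For the 10 pairwise comparisons, 10 splits cannot give a share under 0.05. The real split gave 16410, 18914 and 19592 genes in Col-0 and 18908, 20165 and 19264 in med14 at 4, 8 and 12 h, with 1, 1, 0, 2, 5 and 1 genes in the highest other split. Between genotypes it gave 9471, 16019, 15751 and 13699 genes at 0, 4, 8 and 12 h, with 43, 2, 37 and 3 in the highest other.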

How the results depend on the processing

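Normexp with one background per array was the alternative chosen only after the data were seen. The counts of genes of the 13 comparisons and the 12 overlaps stayed within 1.5 times under the authors' values, quantile normalization, all filters and probe rules, an intensity trend and that alternative, and without any 1 array. Of 212 values of named genes, direction and side of the threshold stayed for 207 with quantile normalization, 203 with normexp and one background, 191 of 206 with the authors' values, 179 with normexp and 118 of 145 with slide as a fixed block. The replicate block left all 212 as they were. Of 86 list results, they stayed for 83 with quantile normalization, 81 with the authors' values, 81 with normexp and one background and 47 of 51 with slide as a fixed block. A gene that a filter removed gave no value there, nor did the seed markers with genes well above background on all 24 arrays. The cause was not tested for any change below, except where it is stated.

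The estimated inter-gene correlation changed the most list calls. In Col-0 at 4 h, lists no longer past the threshold had adjusted p = 0.32 (pathogenesis-related), 0.0869 (jasmonate), 0.192 (cell cycle), 0.0741 (senescence), 0.155 (ribosomal proteins) and 0.0903 (glutathione S-transferases). At 8 h these were 0.0844 (SA), 0.501 (photosynthesis), 0.155 (endoplasmic reticulum) and 0.119 (morning clock), and at 12 h 0.363 (photosynthesis), 0.36 (aliphatic glucosinolates), 0.205 (auxin) and 0.131 (morning clock). In med14 at 4 h they were 0.0592 (SA and pattern-triggered immunity), 0.0638 (pathogenesis-related), 0.544 (photosynthesis), 0.296 (cell cycle), 0.357 (vascular) and 0.529 (histones). In med14 they were at 8 h 0.14 (endoplasmic reticulum and morning clock) and 0.377 (photosynthesis), and at 12 h 0.284 (photosynthesis), 0.179 (cold), 0.12 (morning clock) and 0.177 (evening clock). Between genotypes at 0 h they were 0.137 (ribosomal proteins), 0.495 (endoplasmic reticulum), 0.215 (cold), 0.29 (jasmonate and ethylene defence), 0.699 (jasmonate), 0.146 (morning clock) and 0.0959 (evening clock). At 4 h they were 0.0923 (SA, pathogenesis-related, jasmonate and ethylene defence, TIR-NBS-LRR), 0.275 (jasmonate), 0.148 (pattern-triggered immunity and wall-associated kinases), 0.455 (photosynthesis) and 0.173 (cysteine-rich kinases). At 8 h they were 0.573 (photosynthesis), 0.558 (jasmonate and ethylene defence) and 0.526 (ribosomal proteins). At 12 h they were 0.262 (jasmonate and ethylene defence, abscisic acid), 0.436 (aliphatic), 0.283 (camalexin) and 0.671 (photosynthesis). For the difference of changes they were 0.187 (SA, pathogenesis-related and heat shock), 0.216 (pattern-triggered immunity, endoplasmic reticulum, ribosomal proteins) and 0.478 (photosynthesis) at 4 h, 0.513 (photosynthesis) and 0.0714 (ribosomal proteins) at 8 h, and 0.066 (cold and ribosomal proteins) and 0.0562 (evening clock) at 12 h. The construction is the cause here, since this p allows for genes of a list that vary together.

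With fry, which does not compare a list with other genes, lists newly past the threshold were the evening clock in Col-0 at 12 h (adjusted p = 5.72e-12), ribosomal proteins in med14 at 4 h (0.022), and SA (0.0306), Mediator (0.00183) and reference genes (0.000322) at 0 h. So were the epidermis at 4 h (4.52e-06), SA at 8 h (0.015), guard cells at 12 h (0.00136) and the SA difference of changes at 12 h (0.0426).

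The larger of the numbers of genes up and down became the smaller with quantile normalization and the authors' values in Col-0 at 12 h, in med14 at 8 and 12 h, between genotypes at 0 and 8 h and in the difference at 8 h. So it did with normexp in Col-0 at 12 h, between genotypes at 12 h and in the differences at 4 and 12 h, with genes above background on all 24 arrays between genotypes and in the difference at 8 h, with slide as a fixed block in the differences at 4 and 8 h, and with at least 2-fold at 0 and 12 h and in the difference at 12 h.

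At least 2-fold left 7471, 11734 and 12865 genes in Col-0 at 4, 8 and 12 h and 11707 and 12082 in med14 at 4 and 12 h. It left 2310, 6952, 6415 and 4716 between genotypes at 0 to 12 h, and 6211, 5850 and 4787 for the difference of changes, fewer because the threshold is stricter.

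Normexp background gave 9103, 11974 and 12390 genes in Col-0, 10190, 12968 and 12225 in med14, 3135, 6804, 6465 and 4563 between genotypes and 3697, 4010 and 4023 for the difference of changes. The overlaps (higher, then lower) were 711 and 714 for 0 and 4 h, 547 and 530 for 0 and 8 h and 383 and 278 for 0 and 12 h. They were 1334 and 2240 for 4 and 8 h, 555 and 969 for 4 and 12 h, and 1126 and 1321 for 8 and 12 h. The slope at 4 h was 1.21. These losses follow from spots whose local background lay far above their signal (lowest difference -65473.3 on Col-0 4 h replicate 2), since with one background per array no count moved by 1.5 times. PR1 in Col-0 at 4 h turned to 1.09, PR5 in Col-0 at 8 h to 0.06, and MED14 in med14 to 0.04 at 4 h and -0.02 at 8 h. So did TOC1 in med14 at 12 h to 0.03, PR1 at 0 h to 1.12 and PDF1.2a at 12 h to -0.25. The differences of changes turned for PDF1.2a at 4 h (-1.23), ICS1 (-0.21) and PAD3 (-0.38) at 8 h and WRKY70 at 12 h (0.04), and 22 further calls of named genes ended, MED14 at 0 h (1.16, adjusted p = 0.127), WRKY38 and NPR1 in the differences at 12 h, and those given in the report. Lists lost were pathogenesis-related (0.219) in Col-0 at 4 h, the morning clock in Col-0 (0.0518) and med14 (0.103) at 8 h and at 0 h (0.0552), auxin (0.133) and the cell cycle in med14 at 4 h (0.0889). Photosynthesis in Col-0 at 4 h (8.55e-06), SA (0.000791) and reference genes (0.000272) at 0 h and SA at 8 h (0.00508) were gained, and seed markers (0.658), SA at 12 h (0.44) and MYB (0.591) turned.

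With normexp and one background, PR1 in Col-0 at 4 h (0.13), PR5 in Col-0 at 8 h (0.10), TOC1 (0.06), FMO1 at 0 h (-0.05), PDF1.2a in the difference at 4 h (-0.44) and seed markers (adjusted p = 0.977) turned. MED14 at 0 h (1.05), pathogenesis-related (0.0998) and auxin (0.0923) lost their calls, and SA gained one at 8 h (0.00746) and in the difference at 12 h (0.0272).

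With the authors' values, MED14 in med14 at 4 h (0.05), TOC1 (0.08), ATML1 at 4 h (0.02), PDF1.2a (-0.46) and ICS1 (-0.35) in the differences at 4 and 8 h and MYB (adjusted p = 0.979) turned. MED14 at 0 h (0.66, adjusted p = 0.124), pathogenesis-related (0.188) and jasmonate and ethylene defence at 8 h (0.0553) were lost. Reference genes at 0 h (0.0465) and SA at 8 h (0.0262) were gained, and the slope at 12 h was 1.00. With quantile normalization PR2 at 8 h (0.04) and MYB (0.973) turned, pathogenesis-related was lost (0.0706) and SA at 8 h gained (0.0212).

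With genes well above background on all 24 arrays, lists lost were pathogenesis-related (0.109) and heat shock (0.0615) in Col-0 at 4 h, the morning clock in Col-0 (0.0906) and med14 (0.221) at 8 h and at 0 h (0.13), and auxin (0.157) and vascular (0.0764). So were jasmonate and ethylene defence at 0 h (0.0859) and 8 h (0.174). SA was gained at 0 h (0.00566) and in the difference at 12 h (0.0235), MYB (0.562) and SA in the difference at 8 h (0.882) turned, and the slope at 12 h was 0.95. The mean of all probes turned the ICS1 difference at 8 h (-0.04) and seed markers (0.775), lost vascular (0.0804) and gained reference genes (0.0322) and the SA difference at 12 h (0.0305). Without a filter SA (0.0448) and reference genes (0.0448) at 0 h, SA at 8 h (0.0159) and in the difference at 12 h (0.0142) were gained. An intensity trend gained SA at 0 h (0.0483) and in the difference at 12 h (0.0486).

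The arrays compared alone lost MED14 at 0 h (1.64, adjusted p = 0.214), pathogenesis-related (0.0539), auxin (0.079), and at 0 h jasmonate and ethylene defence (0.0571) and jasmonate (0.0616). They turned seed markers (0.729) and gained the epidermis at 4 h (0.0274) and SA at 8 h (0.019). The replicate block lost auxin (0.0535), although the replicate numbers do not pair samples, since arrays with one number had a median correlation of -0.03 over 84 pairs and others 0.00 over 168.

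Slide as a fixed block gave 12728 genes in med14 at 12 h and 7341, 3794 and 3666 for the differences of changes. It turned PR1 in Col-0 at 4 h (0.21), PR5 in Col-0 at 8 h (0.07), MED14 in med14 at 8 h (-0.21) and 12 h (-0.25) and TOC1 (0.10). In the differences it turned ICS1 at 8 h (-1.06, adjusted p = 0.0101) and 12 h (-0.12), PAD3 at 8 h (-0.50) and PR1 at 12 h (-2.58). Pathogenesis-related (0.065) and vascular (0.0601) were lost, and the SA difference turned at 8 h (0.00365) and passed at 12 h (3.38e-05). Slide as a random block gave 5838 genes at 0 h, and overlaps of 1598 (0 and 4 h, lower), 1295 (0 and 8 h, lower), 1210 and 971 (0 and 12 h, higher and lower). MED14 at 0 h was then at 1.74 and SA at 0 h at an adjusted p of 0.00292.

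Leaving out each array in turn, MED14 lay between 0.68 and 2.58 at 0 h. It lay in med14 between -0.12 and 0.02 at 4 h and -0.06 and 0.05 at 12 h. PR1 in Col-0 at 4 h lay between -0.67 and 0.08, PR5 in Col-0 at 8 h between -0.14 and 0.05, and TOC1 between -0.18 and 0.00. PR2 lay between genotypes between -0.15 and 0.37 at 0 h, -0.52 and 0.16 at 8 h and -0.39 and 0.04 at 12 h. The differences lay between -0.37 and 1.70 for PDF1.2a at 4 h, -0.10 and 0.13 for ICS1 at 8 h and -0.03 and 0.37 for PAD3 at 8 h. Adjusted p lay between 0.0347 and 0.0633 for pathogenesis-related, 0.0337 and 0.0576 for vascular, 8.38e-06 and 0.0795 for jasmonate at 0 h, and 0.00752 and 0.249 for SA at 0 h. It lay between 0.906 and 0.969 for seed markers, 0.513 and 0.974 for the SA difference at 8 h, 0.0112 and 0.126 at 12 h, and 0.868 and 0.993 for MYB.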

Other observations

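On arrays labelled med14 FLC, a repressor of flowering, had log2 differences of -3.29, -3.92, -4.09 and -4.11 at 0, 4, 8 and 12 h, and the floral gene SEP1 of 3.86, 4.24, 4.81 and 4.52. The developmental stage of the plants was not tested, and it bears on every comparison between genotypes.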
